A study of Larimichthys crocea with 2 samples.

How the data were processed

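Total RNA from muscle of large yellow croaker was extracted with Trizol and made into TruSeq libraries, sequenced on an Illumina instrument, per the labels' protocols. There were 2 libraries, 1 from fish without treatment and 1 from fish fasted for 21 days, taken to their groups from the treatment label. The submitters' processing notes name TopHat, TopHat2 2.0.12, SAMtools 0.1.19 and HTSeq, with no role given for each. The genome build, the annotation release and whether counting used strand are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be told apart. Positions are on scaffolds as the files name them. A further RPKM table and region lists that repeat the same values were not used here.

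The authors deposited RPKM per gene for both libraries, with a protein name and position for each gene. The authors' comparison table, deposited with RPM values (reads scaled to a common total), holds 16883 genes with a fold change, a log2 fold change, a p-value, an adjusted p-value and a call, per the file headers. How those p-values were made from 1 library per group is not given in the sources used here, and the adjusted p in the authors' deposited table lies below the p for 12136 genes, so the calls are described only as theirs. Lists of splicing events, deposited with an FPKM for each, and of exons outside the annotation, with start and end coordinates, come as 1 file per library, and a table of ontology terms gives the count of genes the authors called higher or lower.

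Reads per gene were recovered from the deposited RPM, whose values are whole multiples of 1 step in each library. Within a tolerance of 0.1 read, 100% of the 16725 control values and 16599 fasted values above the zero level came out whole. Genes listed with no reads numbered 158 and 284. Depth was 27519918 and 26593839 reads, so 3 reads, used as the floor for a gene with 0 reads, equal 0.109 and 0.113 RPM. The event files were checked against the RPKM table: the log2 ratio of first-exon FPKM correlated with that of RPKM across 7351 genes at Pearson r = 0.889, where genes are not independent replicates.

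The ratio of a gene was log2 of fasted over control RPKM with a pseudocount of 0.5 RPKM added to each, which understates the change of low genes. Genes with a mean of at least 1 RPKM entered. The rule fixed before the data were examined was to use RPKM as deposited if the median ratio lay within 0.1 of 0 and otherwise to centre on it, and at 0.48 it was centred. Genes were called at a fixed size of 2-fold. With 1 library per group no dispersion can be estimated, so no count test was run on the recovered reads and no p-value of own is given. Read ratios of single genes carry 95% exact Clopper-Pearson intervals, conditional on the sum and centred likewise, and shares carry 95% Wilson intervals. Both cover counting error only, since 1 library per group shows no variation between libraries. Reads without molecular identifiers are not independent molecules, so the read intervals can be too narrow even for counting error.

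The 38 gene lists were fixed as name patterns before the data were examined, and proteins that only contained the words were removed by name before values were seen. A list with at least 5 entering members was described by its median and by the percentile of that median among 10000 random lists of the same size, drawn from other genes and matched in 20 bins of mean RPKM. A median outside the 2.5th to 97.5th percentile is said to stand apart, as a description of these libraries. Named genes follow a fixed rule: the 12 largest and 12 smallest ratios among genes with a named protein and at least 5 RPKM in the higher library, with at most 2 genes of 1 name; up to 2 members at each end of each list; a fixed set of muscle and fasting genes; and the 5 most abundant genes of each library. TRIM63, PDK4 and CPT1B were on the fixed set but no gene carried those names, and only part of the genes so chosen is written out.

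Event types were grouped as first exon, last exon, exon skipping, intron retention and alternative exon ends. The 2 forms of an exon skipping or intron retention event were counted once, and all other events were counted as listed. Regions outside the annotation were compared between libraries by scaffold, strand where given, and overlap of at least 50% of each. Alternatives covered the pseudocount, the filter, 3 other scalings, the size threshold, reads in place of RPKM, the matching of random lists, the choice of events and the overlap.

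The steps were tested on simulated read counts for 11922 genes with Poisson counting noise only, so without differences between fish or pieces of tissue. They started from the depths of these libraries, with 200 genes changed. A shift of 0.5 on the log2 scale was added to the fasted library, of which 0.47 was recovered. For this comparison, all 33 genes at 8-fold higher, all 26 at 8-fold lower and all 33 each at 4-fold higher and lower were called. At 2-fold, only 6 of 33 higher and 8 of 32 lower genes were called. Their median recovered log2 ratios were 0.92 and -0.91, short of the threshold, so true 2-fold changes are mostly missed. Of 11732 unchanged genes 4 were called, 95.7% of 2385 exact intervals held the true ratio, and 10 of 200 random lists lay outside the 2.5th to 97.5th percentile. With counting noise alone, the 4 calls do not measure false calls between real animals. The 200 lists were random like those they were set against, so they test the calculation only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.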

Results

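Muscle of the large yellow croaker (Larimichthys crocea), a marine food fish, was profiled by RNA sequencing after 21 days of fasting and without fasting. The labels give 1 control library and 1 fasted library, and how many fish went into each is not given in the sources used here. Which muscle was taken is not given either. Reads assigned to listed genes numbered 27519918 in the control library and 26593839 in the fasted library. With 1 library per group there are no replicates, so no difference below has a replicate check, and each value describes these libraries. The 5 most abundant genes took 31.2% of reads in the control library and 25.9% in the fasted one, and the 20 most abundant took 59.1% and 43.9%.

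The first comparison asked which genes differed between fasted and control muscle. A receptor of selective autophagy, the ubiquitin ligase atrogin-1, the proteasome and the machinery of protein synthesis had higher values in the fasted library. Enzymes of glycolysis, parvalbumins, slow-fibre proteins, most extracellular matrix genes and hemoglobins had lower values. Of 22321 genes, 11417 had a mean of at least 1 RPKM and entered the comparison. The median gene had a log2 ratio of fasted over control RPKM of 0.48 as deposited, which is 1.40-fold, and every ratio below is given relative to that shift. On this scale 1843 genes were at least 2-fold higher and 1892 at least 2-fold lower, and 7682 lay between. With RPKM as deposited the split was 3389 higher and 1014 lower. The share of higher genes among those past 2-fold was thus 49.3% on the centred scale and 77.0% as deposited, and it was 41.6% (1577 higher, 2216 lower) when the 20 most abundant genes were left out of the scaling.

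Among genes with a named protein and at least 5 RPKM in the higher library, the largest ratio was that of calcium-binding and coiled-coil domain-containing protein 1, a receptor of selective autophagy. It stood at 5.45 RPKM in the control and 815 in the fasted library (gene13363, scaffold NW_011322970.1, bases 107898 to 112066, log2 ratio 6.62). The interval of its read ratio, which covers counting error only, ran from 6.55 to 6.94. Ubiquitin-conjugating enzyme E2 G1 stood at 21.2 and 601 RPKM (gene12610, log2 ratio 4.31), with the other 2 genes of that name at 0.47 (gene15901) and 0.35 (gene10863), and Tribbles homolog 2, a pseudokinase, at 7.58 and 215 RPKM (gene3052, 4.25), while the other Tribbles 2 gene had a ratio of -2.29. BNIP3, a mitochondrial protein that recruits the autophagy machinery, stood at 14.9 and 358 RPKM (gene1355, 4.06, 1 of 2 genes of that name). The beta-2 subunit of AMP-activated protein kinase, the cell's energy sensor, had 1 control read and 139 fasted reads (gene9423, log2 ratio 4.29). Its log2 read ratio, which has no pseudocount, was 6.69 (counting interval 4.18 to 11.9995). The other gene of that name (gene9424) had a ratio of 0.05. Regulator of cell cycle RGCC had a log2 ratio of 4.25 and muscular LMNA-interacting protein 3.95. The rest of the 12 largest, between 3.93 and 4.11, included cytoskeleton-associated protein 2-like and the RNA helicase DDX55. The others were zinc finger protein 26, WD repeat-containing protein 82 and T-complex protein 1 subunit theta, each 1 of 2 genes of that name. This T-complex gene (gene16940) had 0 control reads and 100 fasted reads. That is 24.7-fold higher on the centred scale with the control set to the floor of 3 reads (counting interval of the log2 ratio 4.30 and above). The other gene of that name lies beside it (gene16941, 2390 and 12186 reads, log2 ratio 1.91), so the 2 could be parts of 1 gene.

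At the other end, slow skeletal troponin I, the inhibitory subunit of the slow-fibre thin filament, stood at 158 RPKM in the control and 0.0692 in the fasted library (gene2739, log2 ratio -8.61). Its reads numbered 2368 and 1, with a counting interval of the log2 read ratio of -16.95 to -9.16, which has no pseudocount. A cardiac-type myosin regulatory light chain 2B stood at 928 and 3.26 RPKM (gene3992, -8.43). A parvalbumin beta gene, which codes for a calcium buffer of fast fibres, stood at 54808 and 355 RPKM (gene3144, -7.75, counting interval -7.80 to -7.70). Liver-expressed antimicrobial peptide 2 stood at 486 and 3.89 RPKM (gene18946, -7.27). L-serine dehydratase had 1466 control reads and 0 fasted reads, which is 659.9-fold lower with the fasted library set to the floor of 3 reads (counting interval of the log2 ratio -9.07 and below). The lipid-storage genes diacylglycerol O-acyltransferase 2 (-7.14, 1593 and 1 reads) and CIDE-3 (-7.05, also on the adipocyte list) followed. For the former the counting interval of the log2 read ratio, which has no pseudocount, was -16.38 to -8.59. The others were a cardiac troponin T (-6.60), calsequestrin-1, the calcium store protein of the sarcoplasmic reticulum (-6.23), lathosterol oxidase (-6.03), synaptotagmin-1 (-5.52) and gamma-synuclein (-5.44). Gene names are those given in the deposited annotation. Where several genes share a name, reads of near-identical copies could have been split between them, so single copies are uncertain. This also holds for genes named below without a count of copies. Among these, autophagy-related protein 9A, angiopoietin-related protein 4, cathepsin D and BHLHE40 are each 1 of 2 genes of that name. Slow troponin I is 1 of 7 genes of that name, of which gene2736 had a ratio of -5.16 and gene3449 of 0.70, and parvalbumin beta is 1 of 4, with gene3887 at -2.34 and gene3886 at -1.70. Other genes of the same name had ratios of 1.07 for the autophagy receptor (gene1627), 0.14 for diacylglycerol O-acyltransferase 2 (gene21096) and -1.06 for calsequestrin-1 (gene17260).

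**Figure D1:**
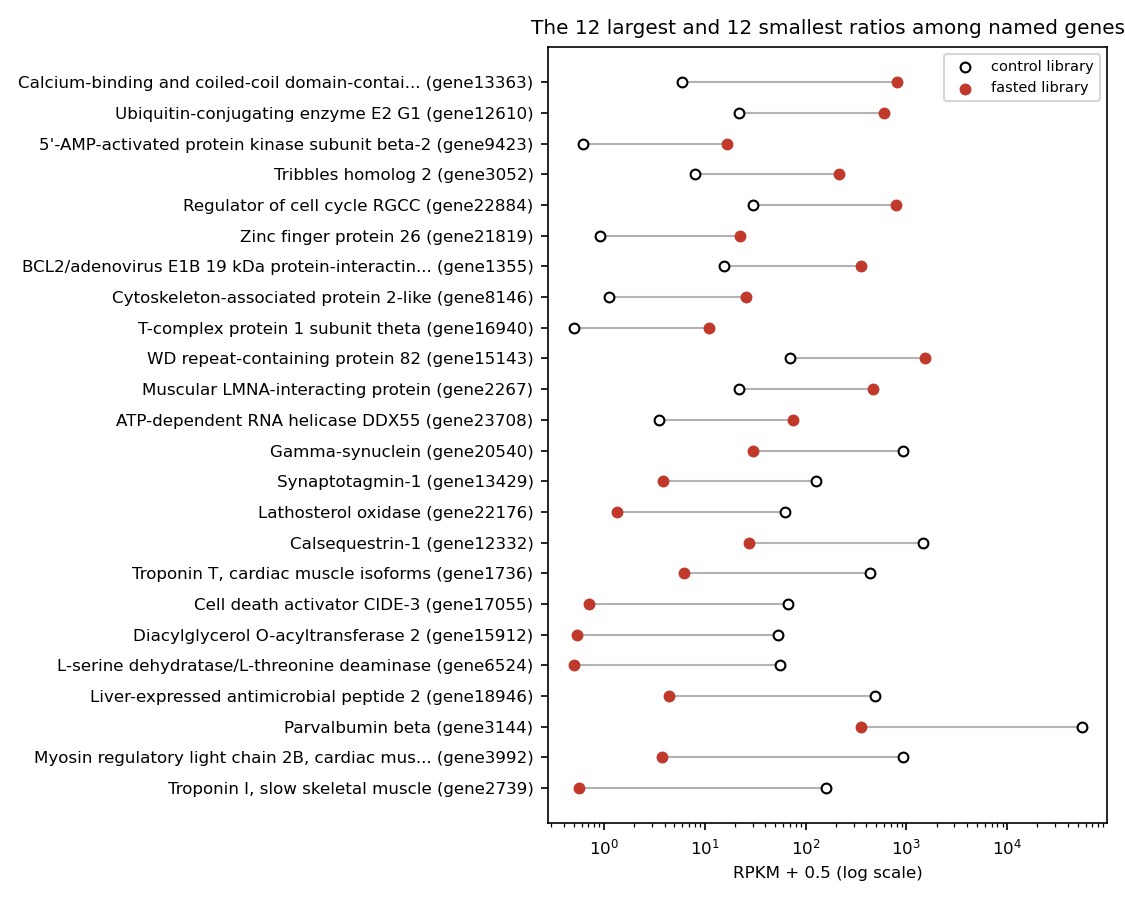
RPKM plus 0.5, on a log axis, in the control library (open points) and the fasted library (filled points) for the 12 named genes with the largest and the 12 with the smallest centred log2 ratio. Each line joins the values of 1 gene, from 5.45 and 815 RPKM at the top to 158 and 0.0692 RPKM at the bottom.

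Proteasome and autophagy genes, which serve protein breakdown, had higher values in the fasted library. Of 49 proteasome subunit genes, 43 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 ratio of 2.14. That median lay above all 10000 random lists matched on mean RPKM, whose central 95% ran from -0.08 to 0.81. The non-ATPase regulatory subunit 8 stood at 43.5 and 547 RPKM (log2 ratio 3.15) and subunit alpha type-5 at 44.4 and 533 RPKM (3.09), while the subunit beta type-6-B like gene had a ratio of -1.13. Autophagy genes had a median of 0.94, at the 99.96th percentile, with 13 of 29 members at least 2-fold higher and 0 lower. Autophagy-related protein 9A had a log2 ratio of 2.75, and GABARAP, which decorates autophagosome membranes, stood at 131 and 972 RPKM (2.40). Vacuole membrane protein 1 (0.34) and autophagy protein 5 (0.08) stayed within 2-fold.

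The atrophy-linked ubiquitin ligases did not stand apart as a list (median 0.22, percentile 62.8), but 6 of 19 members were at least 2-fold higher and 0 lower. F-box only protein 32, known as atrogin-1 and induced in muscle wasting, had 1478 control and 17962 fasted reads (gene10714, scaffold NW_011322784.1, bases 218422 to 224410, log2 ratio 3.16, counting interval 3.09 to 3.25). The mitochondrial ubiquitin ligase MUL1 had a ratio of 3.03, and the lowest members with at least 5 RPKM were AN1-type zinc finger protein 5 (-0.44) and TRIM55 (-0.55). Cathepsins and calpains went both ways, with 4 of 23 higher and 4 lower and a median of 0.30 (percentile 68.6). The lysosomal proteases cathepsin L1 and cathepsin D had ratios of 1.85 and 1.71, and calpain-5 had a ratio of -2.13. Of the 23 genes, 10 were higher and 3 lower with RPKM as deposited.

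Genes of protein synthesis had higher values as well, in each of the 4 lists fixed for it. Ribosome biogenesis factors had a median log2 ratio of 1.60, with 47 of 52 members at least 2-fold higher. Aminoacyl-tRNA synthetases, which charge tRNAs, had a median of 1.23 with 21 of 35 members higher, and translation factors 1.15 with 31 of 53. Cytosolic ribosomal proteins had a median of 1.05 with 54 of 91 higher, and 82 with RPKM as deposited. Members at least 2-fold lower numbered 0 for ribosome biogenesis and translation factors and 1 in each of the other lists. The medians lay at or above the 99.96th percentile of matched random lists. The U3 small nucleolar RNA-associated protein 18 stood at 5.02 and 74.0 RPKM (log2 ratio 3.27), and MPP10, of the same processing complex, at 2.94 and 45.9 RPKM (3.27). Initiation factor 6 had a ratio of 2.40, initiation factor 5B 2.29, aspartate--tRNA ligase 2.11 and a ribosomal protein L5 gene 1.98. The 4E-binding protein 1, a repressor of cap-dependent translation that acts when growth signals are low, stood at 22.7 and 379 RPKM in 1 copy (gene5027, 3.55) and at 16.5 and 25.7 RPKM in the other (gene5256, 0.15).

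**Figure D2:**
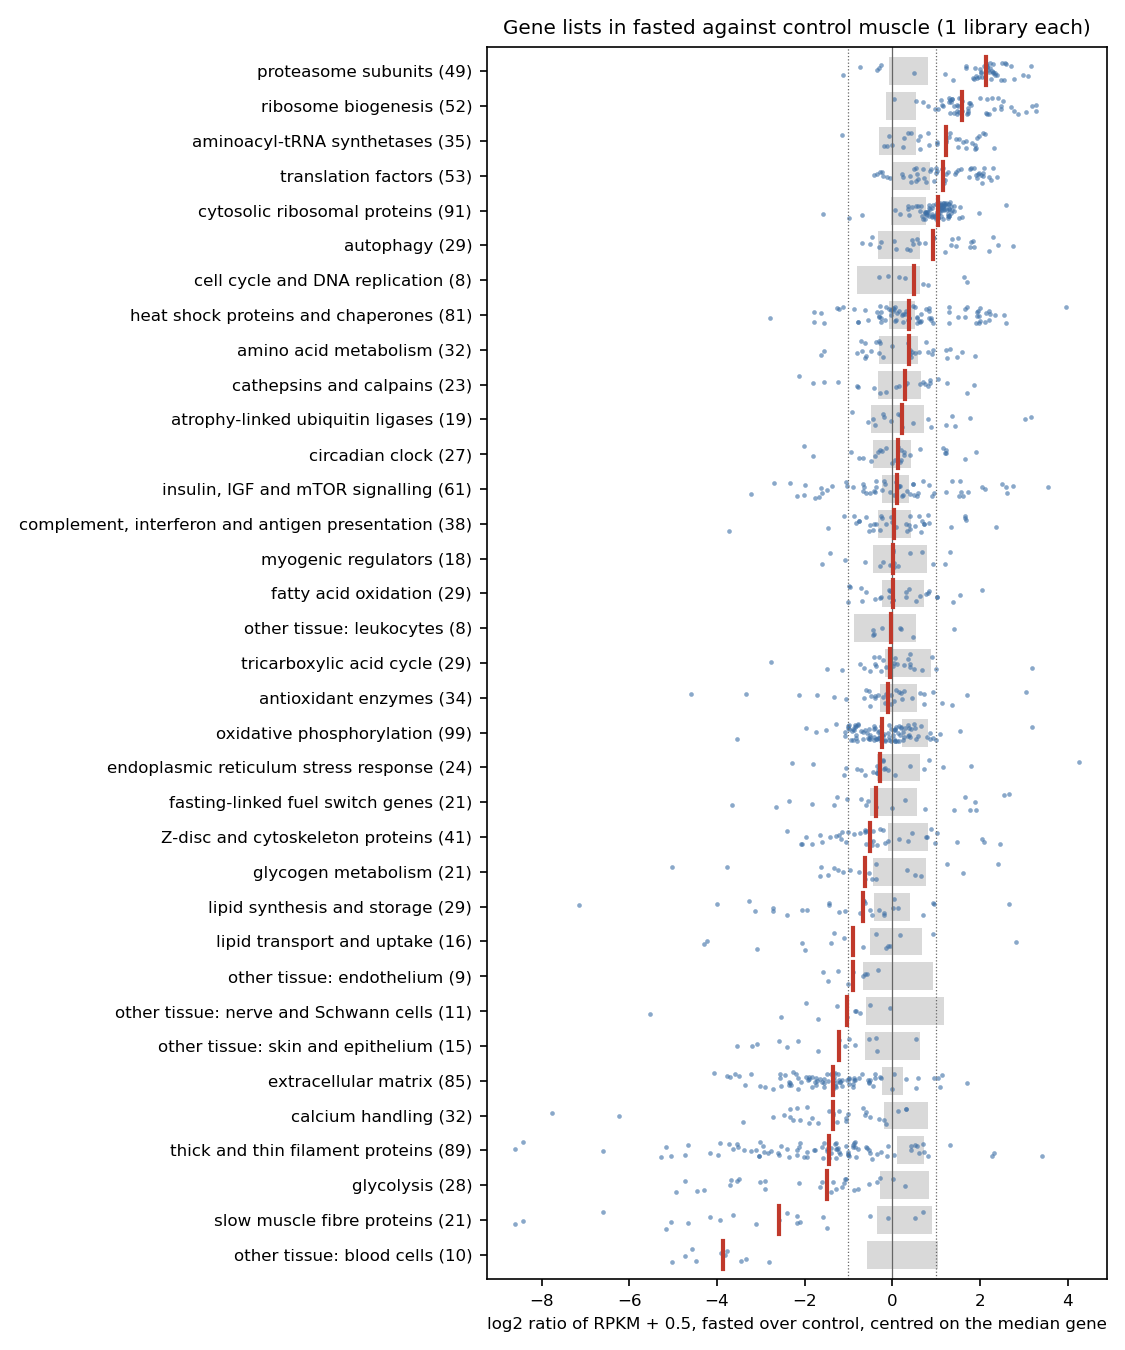
Centred log2 ratio of RPKM plus 0.5, fasted over control, for every entering member (points) of the gene lists, with the median of each list (thick line) and the central 95% of medians of 10000 matched random lists (grey bar). Dotted lines mark 2-fold, and the number after each name is that of entering members. Medians run from 2.14 for proteasome subunits to -3.87 for blood cells.

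Glycolysis moved the other way. Of 28 genes, 21 were at least 2-fold lower and 0 higher, with a median of -1.49, below all 10000 matched random lists. Without centring, 14 were lower and 0 higher. RPKM summed over the list went from 98445 in the control to 14009 in the fasted library. Beta-enolase, the muscle enolase, stood at 9155 and 486 RPKM (log2 ratio -4.72), and aldolase B at 22.6 and 0.554 RPKM (-4.94). The smaller copy of glyceraldehyde-3-phosphate dehydrogenase (-0.36) and alpha-enolase (0.28) stayed within 2-fold. Glycogen metabolism had a median of -0.63 (percentile 0.54) with 8 of 21 members lower and 3 higher, and 4 lower and 5 higher with RPKM as deposited. The debranching enzyme had a ratio of -5.02 and muscle glycogen phosphorylase, which releases glucose units from glycogen, stood at 1858 and 189.5 RPKM (-3.77), while glycogenin-1, the primer of glycogen, stood at 175 and 1300.4 RPKM (2.41, 1 of 3 genes of that name).

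Most genes of mitochondrial fuel use lay within 2-fold. Fatty acid oxidation had a median of 0.01 (percentile 16.7) and the tricarboxylic acid cycle -0.05 (percentile 5.23), with 25 of 29 cycle genes within 2-fold. Oxidative phosphorylation had a median of -0.25, below all matched random lists, with 87 of 99 genes within 2-fold. The sign of that median turned, to 0.24 with RPKM as deposited and 0.064 with no filter. In both settings the list still lay below all matched random lists. With RPKM as deposited this was bound to hold, because that scaling moves all genes alike. Genes of the fasting fuel switch split evenly, 7 of 21 higher and 7 lower (median -0.37, percentile 7.20, and 0.12 with 8 higher and 4 lower with RPKM as deposited), but at a mean RPKM of at least 5 the list stood apart upward, with a median of 1.46 at percentile 99.8. Among them pyruvate dehydrogenase kinase 2, which holds back glucose oxidation, had 3 copies at ratios of 2.66, 1.78 and -0.56, angiopoietin-related protein 4, an inhibitor of lipoprotein lipase, stood at 5.11 and 45.2 RPKM (2.54), and fructose-1,6-bisphosphatase 2 stood at 407 and 44.6 RPKM (-3.66). Lipid synthesis and storage (median -0.66, percentile 0.09, 13 of 29 lower and 1 higher) and lipid transport and uptake (-0.89, percentile 0.21, 8 of 16 lower and 1 higher) stood apart downward. In these lists 9 and 5 genes were lower and 4 and 2 higher with RPKM as deposited. Of the 3 adipocyte genes, CIDE-3 was lower at -7.05 and the other 2 were at least 2-fold higher (median 1.67). Lipoprotein lipase stood at 134 and 21.6 RPKM in its larger copy (-3.09). Perilipin-2, a lipid-droplet coat protein, had a ratio of -3.99 and a fatty acid transport protein 1 gene -4.23, against 2.65 for fatty acid desaturase 6 and 2.81 for a gene of patatin-like phospholipase 2, the adipose triglyceride lipase.

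The contractile apparatus had lower values. Of 89 thick and thin filament genes, 59 were at least 2-fold lower and 4 higher (median -1.44, below all matched random lists). As deposited, 44 were lower and 9 higher. Of the 89, 20 also belong to the slow-fibre list, and without them 43 of 69 were lower and 4 higher (median -1.28). Slow-fibre proteins had a median of -2.58 with 17 of 21 genes lower and 0 higher. Skeletal alpha-actin stood at 115733 and 55199 RPKM (log2 ratio -1.55) and myosin light chain 3 at 51546 and 31001 RPKM (-1.22). A fast skeletal myosin heavy chain gene, among the 5 most abundant of the fasted library and 1 of 16 genes of that name, stood at 13876 and 34088 RPKM (0.81). A fast troponin I gene had a ratio of 3.42 and leiomodin-3, a nucleator of actin filaments, 2.33. Calcium handling had a median of -1.36 with 22 of 32 genes lower and 0 higher, and 14 lower and 0 higher with RPKM as deposited. The most abundant parvalbumin beta gene went from 147098 to 40557 RPKM (gene3887, -2.34), whereas the calcium pump SERCA1 (0.31) and ryanodine receptor 1 (0.30) stayed within 2-fold. Creatine kinase M-type had 2 abundant copies at ratios of -0.87 and 0.17. Nucleoside diphosphate kinase B, at 78360 and 37021 RPKM, had a ratio of -1.56. Z-disc and cytoskeleton genes had a median of -0.50 (percentile 0.06, 5 of 41 higher and 14 lower, but a median of -0.02 with 9 higher and 7 lower with RPKM as deposited), from 2.45 for Xin actin-binding repeat-containing protein 1 to -2.40 for a telethonin gene. Blood-cell genes, which mark blood held in the tissue, were lower alongside these groups, with a median of -3.87.

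Myogenic regulators went both ways (2 of 18 higher, 3 lower, median 0.01, percentile 28.1, and 4 higher and 1 lower with RPKM as deposited). Myogenin had a ratio of 0.41, the 2 genes named for MyoD 0.13 and -1.60, myocyte enhancer factor 2C 1.19 and 2A -1.41. Myostatin, the muscle growth inhibitor annotated as growth/differentiation factor 8, stood at 9.32 and 10.8 RPKM (-0.27, counting interval -0.50 to -0.03). The transcription factors FoxO3 (0.10), a FoxO1 gene (-0.37) and the protease calpain-3 (0.85 and 0.15) were also within 2-fold, while the other FoxO1 gene was lower at -1.62 (gene20942, 57 and 16 reads, counting interval -3.17 to -1.45). The signs of ratios this small depended on the scaling for FoxO3, the FoxO1 gene at -0.37 and myostatin. Insulin-like growth factor I stayed under a mean of 1 RPKM, and IGF-binding protein 1 had a ratio of 1.52. Insulin, IGF and mTOR signalling had 14 of 61 genes higher and 14 lower (median 0.10, percentile 56.3). Hamartin had a ratio of 2.74 in 1 of 4 genes of that name (gene22145), DEP domain-containing mTOR-interacting protein -2.33 and IGF-binding protein 5 -3.22.

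The remaining lists of metabolism and stress did not stand apart in the main setting, and the signs of medians near 0 changed with the scaling for antioxidant enzymes, the endoplasmic reticulum stress response and complement. Their medians were 0.38 for amino acid metabolism (6 of 32 higher, 2 lower), 0.39 for heat shock proteins and chaperones (24 of 81 higher, 8 lower, but percentile 99.9 with no matching), -0.28 for the endoplasmic reticulum stress response (3 of 24 higher, 4 lower) and -0.09 for antioxidant enzymes (4 of 34 higher, 6 lower). Cell cycle and DNA replication had 0.49 (2 of 8 higher, 0 lower, but standing apart at 0.17 and percentile 99.7 with no filter), the circadian clock 0.12 (6 of 27 higher, 2 lower), and complement, interferon and antigen presentation 0.04 (5 of 38 higher, 3 lower). Members at least 2-fold higher with RPKM as deposited numbered 12 for amino acid metabolism, 39 for heat shock proteins, 5 for the endoplasmic reticulum stress response, 8 for antioxidant enzymes, 4 for cell cycle and 12 for complement, and those at least 2-fold lower 5 for heat shock proteins, 2 for the endoplasmic reticulum stress response, 4 for antioxidant enzymes and 1 for complement. Thioredoxin, a protein disulfide reductant, stood at 86.2 and 1005 RPKM (log2 ratio 3.05), glutathione S-transferase theta-1 at 38.5 and 1.75 RPKM (-4.60), and alanine aminotransferase 2-like, which moves amino groups onto pyruvate, at 12.5 and 66.3 RPKM (1.88). The clock repressor BHLHE40 had a ratio of 1.90 and period 2 of -2.01.

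Extracellular matrix and most markers of other tissues were lower in the fasted library. Of 85 matrix genes, 56 were at least 2-fold lower and 4 higher (median -1.34, below all matched random lists), and with RPKM as deposited 39 were lower and 7 higher. Collagen alpha-1(XXVIII) had a ratio of -3.76 and a collagen alpha-1(XIX) gene 1.05. All 10 blood-cell genes were at least 2-fold lower, and RPKM summed over the 12 hemoglobin alpha and beta genes went from 568 to 44.7. Skin and epithelium (median -1.22, percentile 0.05, 9 of 15 lower), endothelium (-0.89, percentile 0.82, 4 of 9 lower) and nerve and Schwann cells (-1.04, percentile 0.25, 6 of 11 lower) had 0 members at least 2-fold higher. With no filter on low values the nerve and Schwann median was -0.23 at percentile 3.81, and that list no longer stood apart. With RPKM as deposited 7 skin, 1 endothelium and 4 nerve genes were at least 2-fold lower and 1 skin gene was higher, while blood-cell genes stayed at 10 lower. A keratin 13 gene stood at 644 and 77.3 RPKM (-3.53), cadherin-5 had a ratio of -1.59 and peripheral myelin protein 22 of -2.53. Leukocyte genes had a median of -0.03 (percentile 62.2) with 7 of 8 within 2-fold. The 1 entering gene of liver and plasma proteins was lower at -2.90, and 0 genes of pancreas and gut entered. In all, 20 of the 35 lists with a percentile lay outside the central 95% of random lists, 6 above and 14 below, against 1.75 among random lists. The value of 1.75 holds for lists of unrelated genes and takes genes, not animals, as units. Members of a list can move together and some lists share members, so the 2 numbers make no test of fasting.

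**Figure D3:**
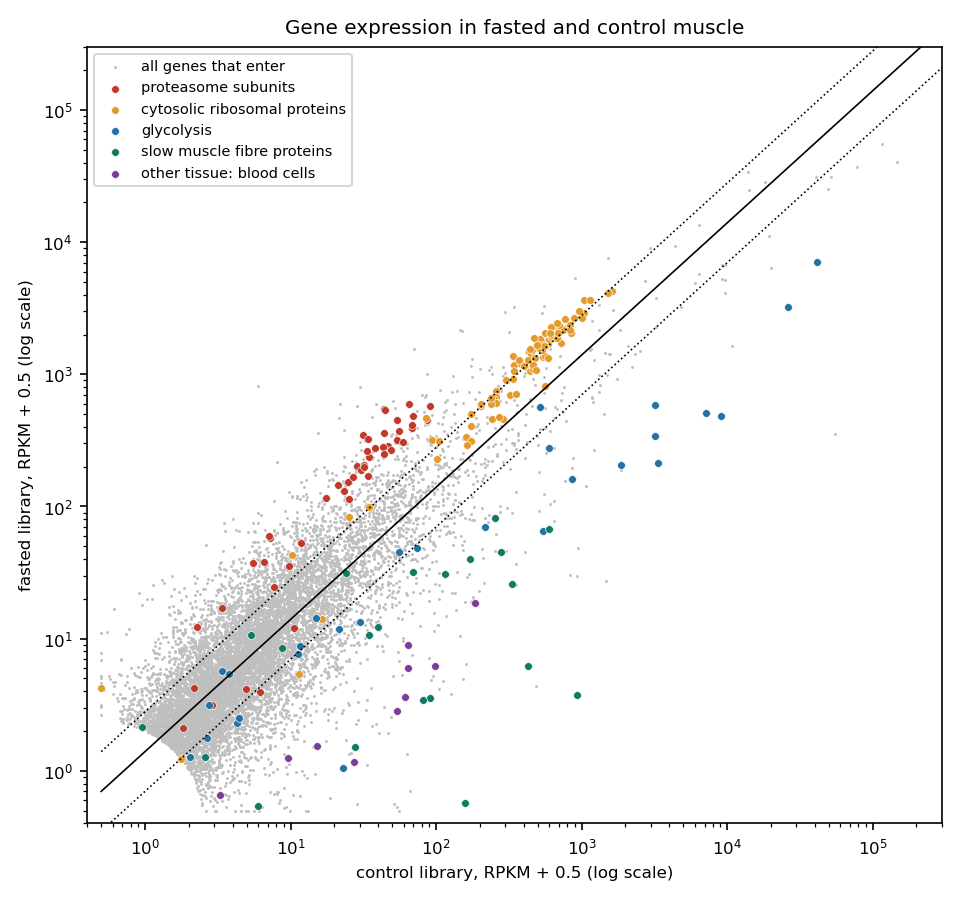
RPKM plus 0.5 in the fasted library against the control library, both on log axes, for the 11417 entering genes (grey) and 5 gene lists (coloured). The solid line marks the median ratio of 1.40-fold as deposited and dotted lines mark 2-fold on either side of it, with proteasome genes mostly above and glycolysis, slow-fibre and blood-cell genes mostly below.

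The authors' deposited table compared the same libraries over 16883 genes. The authors' deposited table calls 5122 genes higher and 2456 lower in the fasted library, on fold changes that are not centred on the median gene. Every called gene there has an absolute log2 fold change of at least 1.00, and the largest adjusted p of a called gene in the authors' deposited table is 0.0455. Of the genes called higher there, 3850 entered here, of which 1843 were at least 2-fold higher and 2007 within 2-fold of the median gene. Of those called lower there, 1242 entered and all 1242 were at least 2-fold lower, and 0 genes had the opposite direction. Both comparisons use the same libraries and centring lowers each ratio by 0.48, so this agreement was largely fixed in advance. In the authors' deposited table of gene ontology terms, metabolic process holds 2429 higher and 788 lower genes, and developmental process 888 and 640. Over all genes that the authors called, 67.6% are higher, and developmental process lies below that share. Some terms hold more lower than higher genes, such as extracellular matrix with 48 higher and 128 lower genes and biological adhesion with 157 and 220.

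The second comparison asked whether the forms of transcripts differed. Deposited lists of events in assembled transcripts held 53691 events in the control library and 54542 in the fasted library. Both forms of an exon skipping or intron retention event were counted once. All other events, alternative exon ends among them, were counted as listed, so the shares are not all in the same unit. Intron retention made up 1.70% of control events (95% Wilson interval 1.59 to 1.81) and 1.99% of fasted events (1.88 to 2.11). Alternative exon ends made up 4.68% (4.50 to 4.86) and 5.05% (4.87 to 5.24), and exon skipping 5.56% (5.37 to 5.76) and 5.49% (5.31 to 5.69). First exons made up 45.8% and 45.8% and last exons 42.2% and 41.7%. Of the first exons, 79.2% in the control and 77.2% in the fasted library came from loci that listed 1 first exon, and of the last exons 91.7% and 91.3% from loci that listed 1 last exon. Of the 18673 reference genes with events in the control library, 95.5% also had events in the fasted library, and 95.3% of 18698 the other way. The intervals cover counting error only, and the events were listed separately for each library.

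Deposited lists of transcribed regions outside the gene annotation held 4048 regions in the control library and 4498 in the fasted library, each of 1 exon. They covered 2533 kb and 2747 kb, with a median length of 430 and 419 bases. A protein match was given for 348 and 371 of them. Of the control regions 59.5% (95% Wilson interval 58.0 to 61.0) overlapped a fasted region by at least 50% of each, and of the fasted regions 53.8% (52.3 to 55.2) overlapped a control region.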

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

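With 1 library per group nothing could be left out in turn, and depth limits mainly the genes with few reads in 1 library. No paired analysis was possible because each group has 1 library and the ratios come from no test. Alternatives were fixed before the data were examined. Of the 20 alternative gene counts 11 lay within 1.5 times the main ones. Genes at least 2-fold higher numbered 2936 with no filter, 1055 at a mean RPKM of at least 5 and 3389 with RPKM as deposited, and genes at least 2-fold lower 1156 at a mean RPKM of at least 5 and 1014 with RPKM as deposited. At 1.5-fold they were 3144 and 3160 and at 4-fold 445 and 532. Of 243 alternative list medians 238 kept their call, which is whether the list stands apart, and the sign of the median where it does, and 69 of 70 alternative percentiles kept theirs. The 3 other scalings move all genes alike, so under them only the sign of a median could change, not whether the list stands apart. The sign of the median changed in 22 of the 243, 19 of these in lists that stand apart in neither setting. The median of oxidative phosphorylation turned to 0.064 with no filter and 0.24 as deposited, while the list stayed at percentile 0. The fuel switch list stood apart at 1.46 with a mean RPKM of at least 5, cell cycle and DNA replication at 0.17 with no filter, and heat shock proteins at percentile 99.86 with no matching, while nerve and Schwann cells no longer stood apart at -0.23 with no filter. No named gene past 2-fold turned its direction, but 29 of 2110 alternative values of named genes fell below 2-fold and 67 passed it. With events of at least 1 FPKM the control and fasted shares were 42.9% and 42.7% for first exons, 41.3% and 40.7% for last exons, 8.76% and 8.26% for exon skipping and 2.65% and 3.19% for intron retention, with control alternative exon ends at 4.36%. In genes with events in both libraries first exons were 45.3% and 45.2%, exon skipping 5.99% and 5.95%, and control alternative exon ends 4.92%. Regions outside the annotation overlapped for 70.9% and 64.0% at 1 base and for 34.6% and 31.7% at 90% of each. Except where fewer genes or events enter or the threshold itself moved, the cause was not tested.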

Other observations

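The gene families, gene pairs and exons in the next paragraphs were chosen after their values were seen. The families came from a look through 916 phrases of 2 or 3 words that annotated names of at least 8 entering genes share, or from the genes beside them. The chaperonin TRiC, which folds actin and tubulin, had 9 of 9 genes at least 2-fold higher in the fasted library (median log2 ratio 2.13). Its genes belong to the heat shock list, which did not stand apart as a whole. Of the 9 genes, 2 are named for subunit theta and lie side by side (gene16940 and gene16941), so they could be parts of 1 gene. The COP9 signalosome, a regulator of cullin ubiquitin ligases, had 7 of 8 genes higher (median 1.65), and its subunit 3 stood at 28.3 and 574 RPKM (3.83). Initiation factor 3 had 14 of 14 genes higher (1.85), RNA polymerase I 6 of 7 (2.41) and the RNA exosome 8 of 10 (1.36). Mitochondrial ribosomal proteins had 20 of 73 higher and 2 lower (0.67), and E2 ubiquitin-conjugating enzymes 10 of 42 higher and 3 lower (0.37). IGF-binding proteins had 7 of 8 lower and 1 higher (median -1.88), the latter IGF-binding protein 1. Krueppel-like factors had 9 of 20 lower and 3 higher (-0.90). Mitochondrial protein import (3 of 23 higher), deubiquitinases (7 of 43 higher), fatty acid-binding proteins (3 of 4 lower) and voltage-gated potassium channels (4 of 8 lower, 1 higher) were looked at as well. With RPKM as deposited the medians printed here kept their signs, but the genes at least 2-fold higher numbered 42 for mitochondrial ribosomal proteins, 13 for mitochondrial protein import, 15 for E2 enzymes and 11 for deubiquitinases, and those at least 2-fold lower 5 for Krueppel-like factors, 1 for fatty acid-binding proteins and 0 for E2 enzymes and mitochondrial ribosomal proteins.

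Fast troponin I genes lie in a row on scaffold NW_011323102.1 and differed in direction. The gene at bases 83461 to 87880 stood at 10849 RPKM in the control and 1631 in the fasted library (gene14836, log2 ratio -3.22), and the one at 104215 to 107019 at 145 and 2167 RPKM (gene14839, 3.42). The genes between them were both at -1.94. Over all 1404 names carried by exactly 2 entering genes, copies seldom parted in this way: 36 pairs had 1 gene at least 2-fold higher and the other at least 2-fold lower, against a central 95% of 54 to 81 after re-pairing at random. Both copies were higher in 44 pairs and lower in 134, against 11 to 25 and 51 to 76. These ranges take genes, not animals, as units, and reads split between near-identical copies would also make copies move together.

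Among 362 skipped exons listed in both libraries with at least 5 FPKM, the share of the inclusion form was at least 20 percentage points higher in the fasted library for 68 and lower for 50, with a median difference of 0. In nebulin, the thin-filament ruler, an exon at bases 560442 to 560552 of its scaffold went from 27.9% to 86.3% inclusion, and in ribosomal protein S24 an exon at bases 1803839 to 1803859 of its scaffold went from 79.8% to 26.6%. FPKM of assembled forms carry no counts here, so these shares have no interval.

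The tests that follow were chosen after the results were seen, except those on paralogs and on gene length. The lower slow-fibre and blood-cell genes (medians -2.58 and -3.87) were weighed against the piece of tissue taken. The highest of these medians over the 4 scalings was -2.10, so the choice among these scalings does not account for them. Each scaling moves all genes alike, by 0.60 at most from the values as deposited. For medians this low the outcome was therefore fixed once they were known. For the blood-cell genes, a larger share of fast fibres diluting every other cell type alike is argued against by 2 lists. The lowest leukocyte or endothelium gene lay 1.23 above the highest blood-cell gene on the log2 scale. The lowest nerve (-5.52), matrix (-4.07) and skin (-3.53) genes lay below that blood-cell gene (-2.82), so those lists show no such gap. For the slow-fibre genes the difference from the leukocyte and endothelium lists was -2.29, set by the highest slow-fibre gene at 0.70, and cannot decide. The slow-fibre median of -2.58 lay below the lowest endothelium (-1.59) and leukocyte (-0.44) genes. It also lay below the nerve (-1.04), skin (-1.22) and matrix (-1.34) medians. As a set, though not gene by gene, the slow-fibre genes thus argue against equal dilution as the whole cause. Single genes overlap, since the lowest nerve, skin and matrix genes lay below -2.58 and 2 slow-fibre genes lay above 0. A smaller dilution stays open, since 100% of endothelium and nerve, 93.3% of skin and 89.4% of matrix genes lay below 0. Less red muscle in the fasted piece stays open, as does less blood held in it, which was not tested: 81.0% of slow-fibre genes were at least 2-fold lower, fasting could give the same, and with 1 library per group the piece taken and the fast cannot be told apart.

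For the lower glycolysis genes, the median was -1.01 or below under all 4 scalings. The choice among these scalings does not account for it, again an outcome fixed once the median was known. Reads shared between paralogs are argued against because, with the RPKM of all genes of a name summed, the median over 20 names was -2.87. Fewer fast fibres stay open, since the summed RPKM of the fast myosin heavy chain genes had a log2 ratio of 0.65 (0.53 to 1.13 over the scalings), but 6 of their 12 entering genes lay above 0 and 5 were at least 2-fold lower. Other proteins abundant in fast fibres were lower, with summed RPKM at -2.71 for the parvalbumins and -2.02 for fast troponin I. A change within fast fibres during the fast was not tested, and with 1 library per group it cannot be told apart from fewer such fibres.

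For the higher proteasome and protein-synthesis genes, gene length is argued against: after the trend over 20 bins of coding length was taken off, the lowest of the 5 list medians was 0.90. The lowest median under the 4 scalings was 0.93, so the choice among them does not account for these medians, an outcome again fixed once they were known. More leukocytes are argued against by a median of -0.032 for the leukocyte genes (0.45 as deposited), with 1 of 8 at least 2-fold higher. Leukocyte genes were low, at 25.2 control and 45.9 fasted RPKM summed over all 26 of the list. The pseudocount understates changes of such genes, so a smaller rise stays open. GC content, RNA quality, the time of sampling, differences between fish and a response of the muscle to fasting were not tested and stay open.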
